A study of Lacticaseibacillus paracasei with 2 samples.

How the data were processed

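RNA was measured in 2 libraries of Lacticaseibacillus paracasei strain JS1, 1 labelled as grown with fermentation and 1 as grown without it. Per the labels' protocols, total RNA was taken from cultured cells with TRIzol, a reagent that extracts RNA by phenol, and copied into cDNA with a commercial kit. The design text of the series speaks of growth in the presence or absence of a P. lobata extract. The sample titles mark the with-fermentation library as chem and the other as nochem, without saying what these stand for. The labels do not say outright which library had the extract, so the libraries are named here by fermentation alone.

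Bowtie, a read aligner, and Cufflinks, which estimates transcript abundance, are named per the submitters' processing notes. Their versions, the genome build, the strand setting and any removal of ribosomal RNA are not given in the sources used here. The deposited unit is FPKM (fragments scaled by feature length and by the library's mapped fragments), per the file headers, with a lower and an upper bound for each feature. The authors also deposited a coverage value per feature, which was a constant multiple of FPKM within each library (0.503 with fermentation and 2.41 without) and was used only for depth. Each library lists the same 3161 features on 3 contigs, 3087 with coding identifiers and 74 with RNA identifiers. The lengths of the 3087 coding genes are all multiples of 3, so they are coding lengths. Coordinates are given 1-based on the authors' contigs. All features carry the status OK in both libraries.

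The files do not pair the feature identifiers with gene names, and no genome or annotation was used. The 29 gene lists that had been fixed could therefore not be applied, since 0 of them matched a name. The rule for named genes took the coding genes with the highest and lowest ratio, a mean of at least 10 FPKM and authors' bounds that did not overlap. Its demand for an informative annotation could not be applied, and it was limited to 2 genes per direction, given by position. In place of the lists, runs of neighbouring genes were described. A run is at least 3 consecutive coding genes longer than 200 bases that pass the filter on low values, each at least 2-fold different in the same direction with bounds that do not overlap. This definition, and the choice of the 5 longest runs and the 5 with the largest median ratio per direction (18 runs in all), were made after the files were seen to lack names. Runs of equal length were ranked by median ratio, so some runs of 5 genes in each direction are not among the 18. The 2-fold rule, the filter, the pseudocount, the centring and the alternatives not described as added later were chosen before the data were examined.

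For each feature the log2 ratio of FPKM + 1, with over without fermentation, was computed. The median ratio over features with a mean of at least 10 FPKM was subtracted, and a feature was counted as higher or lower at a centred ratio of at least 2-fold. Unless an alternative is named, folds are on this scale, which understates the ratio of features with low values. No fold is given against a feature listed at 0. With 1 library per group no test was run and no p-value or standard error exists, and every difference describes these libraries without a replicate check.

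Depth was recovered from the authors' bounds. The upper bound was read as the FPKM plus 2 standard deviations of a counting error, which implies a number of fragments per feature. Lower bounds stop at 0, as in 297 features above 0 with fermentation and 136 without. Of the implied numbers under 10, 59.6% with fermentation and 61.5% without lay within 0.05 of a whole number. The rest did not, so implied fragments are estimates. A Theil-Sen line of fragments per FPKM on length, over features longer than 500 bases with over 50 fragments, gave 2530881 mapped fragments with fermentation and 12172563 without. Their ratio, 4.81, lies next to the ratio of the coverage constants, 4.79. Against that line, none of the 1212 filtered features longer than 500 bases that share no base with another had under 0.9 of the fragments their FPKM and length predict. Of the 425 that share bases, 95 did with fermentation and 233 without. For these the bounds are wider than counting error alone gives, and their implied fragments are too low. No bound covers variation between cultures.

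The 2-fold rule was tested on simulated data, in which fragments were drawn at the real depths with counting error alone. Changed genes were drawn only from those longer than 200 bases. The rule recovered 98 of 100 genes simulated at 4-fold and 92 of 100 at 8-fold. The 2 and 8 genes missed equal the numbers whose simulated mean lay under the filter. Changes under 4-fold and changed genes of at most 200 bases were not simulated, so recovery is not known for them. In the real data, 104 of 413 higher and 152 of 433 lower features reached 4-fold. Among genes simulated without a difference, 18 of 1967 longer than 200 bases (0.915%) and 49 of 132 of at most 200 bases (37.1%) were counted as 2-fold.

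The alternatives tried were pseudocounts of 0.1 and 10, no filter, a mean of at least 100 FPKM, uncentred values, rescaled values, and bounds that must not overlap. Rescaling left out the RNA features and the 10 most abundant genes of either library, and rescaled ratios were not centred. After the data were seen, 4 were added: genes longer than 200 bases, genes sharing no base with another, at least 20 implied fragments, and thinning of the without-fermentation library to the depth of the other by binomial draws. Depth here means estimated mapped fragments, and the draws were made on implied fragments rounded to whole numbers. Gene order was compared with 1000 shuffled orders, and small contigs with 10000 random lists matched on expression in 20 bins. A further pattern, the block with the lowest ratios, was also tested after its values were seen, and its values are given without weighing. The block was drawn from the lower run with the largest median ratio, at 2582069-2587574, and the lower run near it, at 2571071-2578664. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.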

Results

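The data are 2 transcriptomes of Lacticaseibacillus paracasei JS1, a strain that the series describes as producing equol, a compound that gut bacteria make from soy isoflavones. The library labelled with fermentation had an estimated 2530881 mapped fragments, and the library labelled without fermentation 12172563. Within annotated features the authors' bounds, which give too few fragments for some features that share bases, implied 764842 and 3233311 fragments. The median feature that passed the filter rested on 99.6 fragments with fermentation and 340 without. There were 255 such features with under 10 fragments with fermentation and 99 without. Each condition had 1 library, so no value has a replicate error and no difference was tested.

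The comparison is between the library labelled with fermentation and the one labelled without. The series' design text frames it as the effect of a P. lobata extract in the culture on the expression of each gene. Expression differed widely: of 2333 features with a mean of at least 10 FPKM, 413 (17.7%) were at least 2-fold higher in the with-fermentation library and 433 (18.6%) at least 2-fold lower. Some large differences lay in groups of neighbouring genes. A 4-gene region at 2239844-2245370 of contig 1 was a median of 16.9-fold higher with fermentation, and a block at 2571071-2587574 was a median of 16.4-fold lower. A run of 14 consecutive genes at 1291815-1302299 was a median of 2.83-fold higher.

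These splits are relative to the median feature, which stood 0.39 higher on the log2 scale with fermentation (1.31-fold). On the deposited FPKM without centring, 667 features were at least 2-fold higher and 277 lower, so that 70.7% of the differing features were higher, against 48.8% after centring. The middle 50% of centred ratios ran from -0.72 to 0.73. At least 4-fold differences were found in 104 features higher and 152 lower with fermentation, and at least 8-fold ones in 40 and 68. Among features longer than 200 bases, the at least 4-fold ones were 83 higher and 108 lower. Across features, Pearson's r of log2(FPKM + 1) between the libraries was 0.706 and Spearman's rho 0.761. These are correlations across genes, which are not independent replicates.

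**Figure D1:**
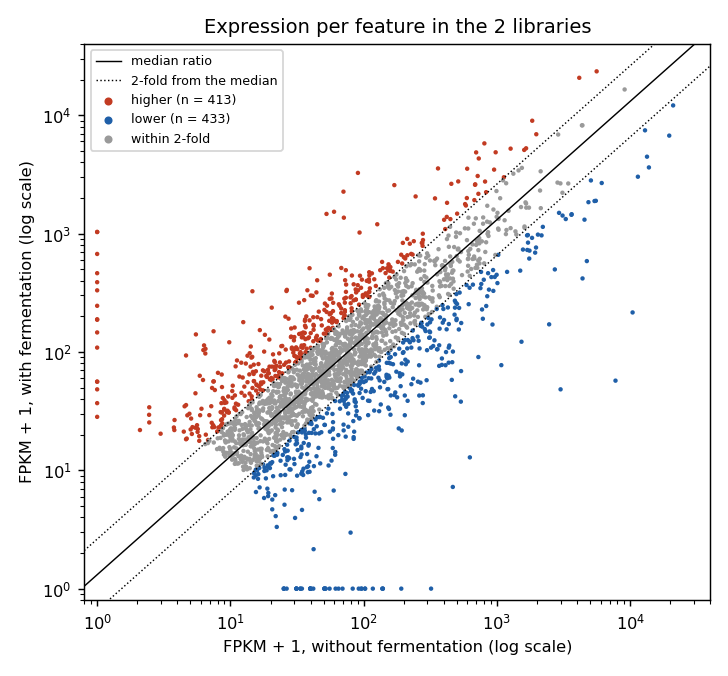
FPKM + 1 of each of the 2333 features that passed the filter, without fermentation (x axis) and with fermentation (y axis), both on log scales. Points at least 2-fold above the median ratio (413) are red, points at least 2-fold under it (433) are blue, and points at the left and bottom edges are features listed at 0 in 1 library.

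The highest values were of similar size in both libraries, 23486 FPKM with fermentation and 20992 without. The 10 most abundant features held 18.6% of the summed FPKM with fermentation and 22.5% without, and 3 features were among the 10 in both. Some of them were short: 4 of the 10 with fermentation and 3 of the 10 without had at most 200 bases. Among coding genes, 225 were listed at 0 in both libraries, 114 at 0 with fermentation alone and 21 at 0 without fermentation alone. Thinning the deeper, without-fermentation library by the ratio of estimated mapped fragments gave 52 and 72, so the excess at 0 with fermentation did not hold. The turn in direction cannot be read as a result at equal depth. Implied fragments within features (764842 with fermentation and 3233311 without) differ by less than that ratio, and they were rounded before the draw. The thinned library may therefore be the shallower one within features. Of the 225, 51 were longer than 500 bases.

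The files do not pair identifiers with gene names, so single genes are given by position on contig 1. The highest ratio by the rule for named genes was that of the coding gene at 1204812-1204952 (141 bases). It had 387 FPKM with fermentation (authors' bounds 40.9 to 734), on 5 fragments, and is listed at 0 without. The next was the coding gene at 1675317-1677002 (1686 bases), at 3255 FPKM with fermentation (3109 to 3401) and 89.5 without (83.7 to 95.3). It was 27.4-fold higher with fermentation and shares bases with a neighbour. The lowest ratio belonged to the coding gene at 383494-383676 (183 bases), listed at 0 with fermentation and at 319 FPKM without (256 to 382). The next, at 2578299-2578664 (366 bases), had 56.2 FPKM with fermentation (35.0 to 77.4) and 7754 without (7638 to 7870), and was 178-fold lower with fermentation. Both genes listed at 0 in a library had at most 200 bases, and their ratios depend on the pseudocount. With one of 10, the gene at 2578299-2578664 (147-fold lower) had a lower ratio than the one at 383494-383676.

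Genes that were higher with fermentation formed 38 runs of at least 3 neighbours, with 146 genes in all. The longest of them, at 1291815-1302299, held 14 genes at a median of 477 FPKM with fermentation and 121 without. Its genes were between 2.33-fold and 6.16-fold higher. The region at 2239844-2245370 held 4 genes at a median of 1445 FPKM with fermentation and 69.7 without, from 8.36-fold to 24.5-fold higher. At 1323233-1326214, 3 genes were a median of 13.7-fold higher, at 148 FPKM against 6.47, and 6.97-fold higher with a pseudocount of 10. The 3 genes at 1675317-1679744 were a median of 11.5-fold higher, at 2567 FPKM against 169, and include the named gene with the 27.4-fold ratio. The 2 stronger genes share bases, and the gene that shares none, at 1677501-1679744, was 2.35-fold higher. The 3 genes at 1898497-1900428 were a median of 5.96-fold higher, at 152 FPKM against 15.6.

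Among the other long runs higher with fermentation, 6 genes at 1194663-1200907 were a median of 2.79-fold higher (102 FPKM against 27.2), and the strongest of them was 9.48-fold higher. Their median was 4.38-fold after the without-fermentation library was thinned to the depth of the other. The 5 genes at 1254286-1257897 were a median of 5.33-fold higher (63.4 FPKM against 12.4), but 3.17-fold with a pseudocount of 10 and 3.36-fold after thinning. The 5 genes at 368670-372182 were a median of 3.54-fold higher (276 FPKM against 54.6). At 255479-260549, 5 genes were a median of 2.88-fold higher (93.8 FPKM against 33.6).

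**Figure D2:**
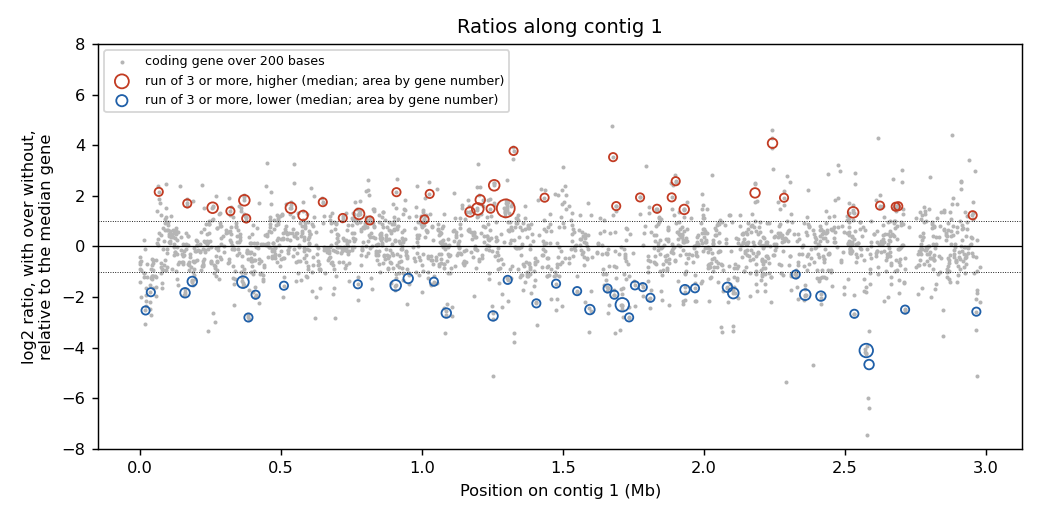
Centred log2 ratio (with over without fermentation) of coding genes longer than 200 bases by position on contig 1 in Mb, with each run of at least 3 genes drawn as a circle at its median ratio and an area that follows its gene number. The 38 runs higher with fermentation (red) and the 38 lower (blue) lie along most of the contig, with the 14-gene run at 1291815 as the biggest circle. No run lies between 2713654 and 2950680.

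Genes that were lower with fermentation also formed 38 runs, with 143 genes in all, the longest of 8 genes. The equal number in both directions holds on centred values: without centring there were 78 runs higher and 26 lower. Of the 38 lower runs, 2 have the same 3 gene lengths and near-equal values (19240-21583 and 2963933-2966276), and were counted as separate runs. The strongest lay close together. The 8 genes at 2571071-2578664 were a median of 17.3-fold lower, at 98.6 FPKM with fermentation and 1302 without, and ranged from 3.05-fold to 178-fold lower. The 4 genes at 2582069-2587574 were a median of 25.5-fold lower, at 47.5 FPKM against 501, and ranged from 2.10-fold to 84.6-fold lower. This median depended on which genes entered: with 3 of the 4 genes left it was 62.8-fold at a mean of at least 100 FPKM and 9.64-fold after rescaling. The first of the 4, at 2582069-2583676, had 215 FPKM with fermentation and 10418 without, a 63.4-fold difference. Together, from 2571071 to 2587574, 13 coding genes longer than 200 bases passed the filter, with a median of 76.3 FPKM with fermentation and 1007 without. Of these, 12 were at least 2-fold lower, and they are the members of the 2 runs that set the block's limits. Each entered its run for being at least 2-fold lower, so this count follows from how the block was drawn.

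The other run of 8 genes, at 1705797-1714311, was a median of 4.95-fold lower with fermentation (44.7 FPKM against 117). The 6 genes at 362576-368193 were abundant in both libraries and a median of 2.66-fold lower (968 FPKM against 1930), and the run that begins at 368670 was higher. The 5 genes at 2356000-2361033 were a median of 3.76-fold lower (176 FPKM against 391), and the 5 at 2101013-2105966 a median of 3.60-fold lower (10.1 FPKM against 29.6). The 3 genes at 383874-386007 were a median of 7.02-fold lower (80.2 FPKM against 433). The 3 genes at 1732725-1735987 were between 5.24-fold and 7.06-fold lower (median 28.5 FPKM against 158). The 4 genes at 1250035-1254035 were a median of 6.72-fold lower (39.7 FPKM against 186), and the run that begins at 1254286 was higher. Of the 4, the 3 that share bases were from 5.17-fold to 7.25-fold lower, and the gene at 1253469-1254035, which shares none, had 1.97 FPKM with fermentation (authors' bounds 0 to 4.77, on 1.99 implied fragments) and 78.7 without (70.6 to 86.8).

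**Figure D3:**
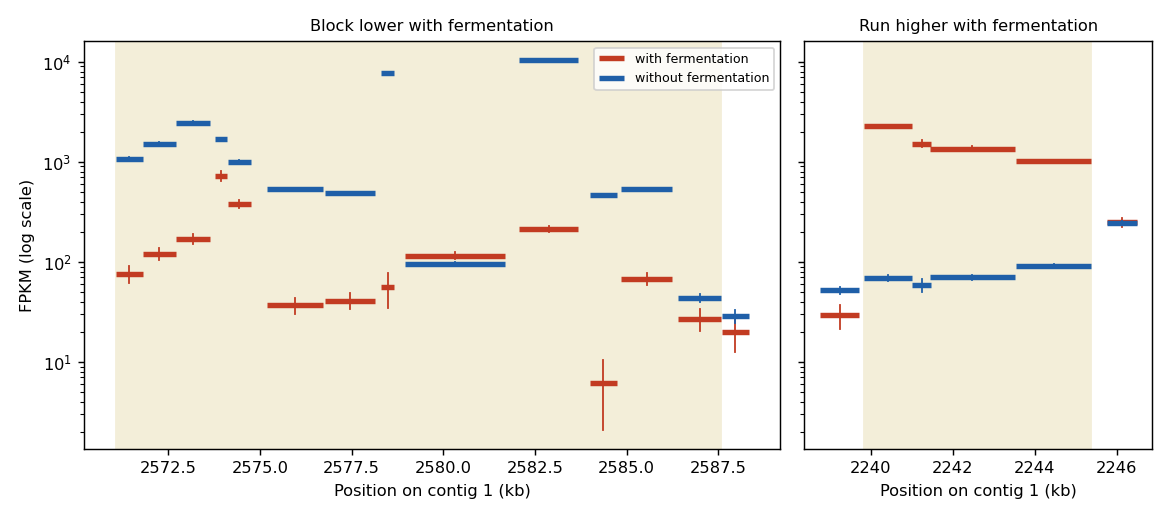
FPKM (log scale) of coding genes longer than 200 bases by position in kb, as horizontal bars over each gene with vertical lines for the authors' bounds, with fermentation in red and without in blue. On the left, 12 of 13 filtered genes of the shaded block at 2571071-2587574 were at least 2-fold lower with fermentation. On the right, the 4 genes of the shaded run at 2239844-2245370 were higher. Genes entered runs, and through them the block, for differing at least 2-fold.

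Features with RNA identifiers held little of the summed FPKM, 0.169% with fermentation and 0.0038% without. Most of the former share came from 1 feature of 117 bases, with 672 FPKM on 1 implied fragment, and without that feature it was 0.064%. FPKM is scaled by length, so these are not shares of fragments. Implied fragments within features were 764842 of an estimated 2530881 mapped with fermentation and 3233311 of 12172563 without. How much RNA-feature sequence each library held is therefore not known. Of the 74 features with RNA identifiers, 66 were listed at 0 in both libraries. The 5 features of 1549 bases summed to 222 FPKM with fermentation and 12.1 without, 13.0-fold higher with fermentation. Each of the 5 was higher, but they are not independent replicates. Most of the sum came from 2 of them, at 103 and 105 FPKM with fermentation against 5.26 and 5.50 without. The other 3 had low values, 3.96 to 5.38 FPKM with fermentation against 0.355 to 0.473 without. The 5 features of 2918 bases summed to 188 FPKM with fermentation and 9.13 without, 14.3-fold higher, from 2 features, while 3 were listed at 0 in both.

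The precision of a ratio depended on gene length. Of the 71 features of at most 150 bases that passed the filter, 87.3% were counted as 2-fold different, on a median of 1.99 fragments over both libraries, and in 85.5% of these the authors' bounds overlapped. Of the 114 features longer than 2000 bases, 31.6% were 2-fold different and 0% of these had overlapping bounds. With the added demand that bounds do not overlap, 371 features were higher and 350 lower with fermentation.

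**Figure D4:**
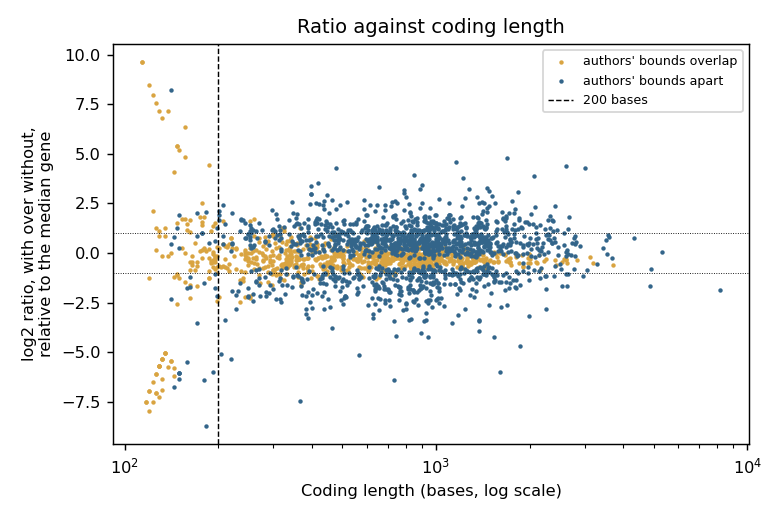
Centred log2 ratio (with over without fermentation) against coding length in bases (log scale) for coding genes that passed the filter, with genes whose authors' bounds overlap in yellow and genes whose bounds are apart in blue. Left of the line at 200 bases the ratios spread widely, with a standard deviation over all features of 5.34 at lengths of at most 150 bases against 1.23 at lengths over 2000.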

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

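Thinning and the alternatives by length, shared bases and fragments were chosen after the data were seen. So were all alternatives for the runs, the block and the genes listed at 0, those for the median ratio except the other filters, and those for the correlation except the pseudocount of 0.1 and no filter. No feature was counted in the opposite direction under any alternative, and no value reversed. An opposite count needs a move from at least 2-fold lower to at least 2-fold higher, or the other way. Apart from thinning, the alternatives shift ratios together, change the pseudocount or drop features, so this was nearly fixed in advance. The counts of higher and lower features stayed within 1.5 times of 413 and 433 except with a mean of at least 100 FPKM (185 higher, 179 lower), which leaves fewer features, and without centring (667 higher, 277 lower), which leaves in the median shift. The median log2 ratio of 0.39 was 0.32 with a pseudocount of 10, 0.20 without a filter and 0.11 after rescaling. The correlation across genes of 0.706 was 0.616 with a pseudocount of 0.1, 0.781 with one of 10, 0.870 without a filter, 0.516 at a mean of at least 100 FPKM and 0.666 after rescaling. It was 0.801 for genes longer than 200 bases, 0.735 for genes sharing no base, 0.801 with at least 20 fragments and 0.685 after thinning. The 38 runs of higher genes became 25 with a pseudocount of 10, 17 at a mean of at least 100 FPKM, 78 without centring and 25 among genes sharing no base. The 38 runs of lower genes became 18 at a mean of at least 100 FPKM and 26 without centring. A mean of at least 100 FPKM left 907 of the 2333 features, and the demand for no shared base left 1720. Lack of centring leaves in the median shift, as for the counts of features. How far these gave the changes in run number was not tested. For the 18 named runs, 140 of 167 alternative medians stayed within the range of the run's own genes and 27 moved beyond it, each in the same direction. Among these 167, medians moved by over 1.5 times in the runs at 1194663, 1254286, 1323233 and 2582069. A further 13 medians were not computed because under 3 genes were left, 7 at a mean of at least 100 FPKM and 6 among genes sharing no base. In 2 of the 13 no gene was left, and in 4 the genes left differed from the run's median by over 1.5 times: 7.01-fold at 1194663 with at least 100 FPKM, and, sharing no base, 35.4-fold at 1250035 (1 gene, on 1.99 fragments with fermentation), 3.21-fold at 1254286 and 2.33-fold at 1675317. The block at 2571071-2587574 kept a median between 12.5-fold and 17.2-fold lower. For the 4 named genes, 26 of 35 alternative ratios stayed within the range that the authors' bounds allow, and 9 moved. Gene list medians, and with them every alternative setting chosen for them, were not run, since no list matched a name. No paired analysis was possible because there is 1 library per group, and for the same reason no library could be left out. Of the 255 filtered features on under 10 fragments in the with-fermentation library, 120 were among the 151 of at most 200 bases and 135 among the 2182 longer ones.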

Other observations

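The comparison of adjacent genes with those 20 apart was planned, the tests of genes sharing no base and of short genes were written before their results were seen, and the tests on shuffled orders, RNA features and the lowest block were chosen after the results were seen.

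The small contigs had median ratios near that of contig 1, but more features listed at 0. With fermentation these were 12 of 33 on contig 2 (36.4%) and 14 of 35 on contig 3 (40.0%), against 379 of 3093 on contig 1 (12.3%), and without fermentation 11, 11 and 291. Contig 2, whose last feature ends at 18616, had 21 features that passed the filter, with a median centred log2 ratio of -0.25, at percentile 20.9 among 10000 random lists of the same size and expression. Contig 3, whose last feature ends at 16810, had 16 such features, and its median lay at percentile 41.8. Along contig 1, in windows of 200000 bases, median ratios were lowest from 1 to 200000 (-0.52, 48 of 167 genes lower and 17 higher) and from 1600001 to 1800000 (-0.44, 37 of 88 lower and 14 higher). The highest median was 0.28, from 1200001 to 1400000, where 48 of 169 genes were higher and 31 lower. The window from 1 to 200000 holds a stretch of genes that recurs further along the same window. Many genes of the copies match in length and order, mostly with similar FPKM. Genes lower in both copies were counted each time, so the 48 lower genes of that window are not all independent. Its median without the copies was not computed.

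A pair of runs lower with fermentation lies near the ends of contig 1, at 19240-21583 and 2963933-2966276. Each spans 2344 bases with 3 genes, and their median FPKM without fermentation was 83.1 in both, against 23.3 and 20.7 with fermentation. Genes in the lowest block were not silent with fermentation, at a median of 76.3 FPKM. Its 10 genes whose authors' bounds are as narrow as their own fragments allow had a median centred log2 ratio of -3.64. Since 12 of the block's 13 genes were chosen for being at least 2-fold lower, that median was bound to be at least 2-fold lower too. It therefore cannot test whether reads shared with other genes gave the decrease.

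Neighbouring genes had similar ratios, with a correlation of 0.33 across 2325 adjacent pairs, which argues against independent noise in each gene, since the highest of 1000 shuffled orders gave 0.07. Reads shared by overlapping genes are argued against as the whole cause by the 2020 adjacent pairs with no shared base, at 0.28 against a highest shuffled value of 0.07. Genes with few bases between them could still share a fragment. Among the 1553 pairs over 50 bases apart the correlation was lower, 0.21 against a highest shuffled value of 0.08. The correlation was 0.64 with at most 50 bases between the genes (467 pairs), 0.12 over 300 bases (519 pairs, highest shuffled value 0.21) and 0.06 between genes 20 apart, and there were 76 runs against a median of 15 and at most 26 in shuffled orders. The longest run of a shuffled order had a median of 4 genes, 3 of the 1000 orders held a run of 8, the length of the longest runs lower with fermentation, and 308 held one of at least 5, so some of the shorter runs may be chance. No biological explanation was tested.

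Long RNA features were higher with fermentation. An uneven split of reads between copies is argued against by sums over all copies of a length, the smaller of which was still 3.70 higher on the log2 scale. The sums of the 1549-base and 2918-base features differed by 0.13, a small difference, as predicted if more stable RNA was carried into the with-fermentation library. These features lie side by side in pairs, so their sums are not independent, and their nearness does not favour this cause over others. Of the 74 RNA features, 66 were listed at 0 in both libraries and could not bear on it. A difference in cellular RNA content between the growth conditions would give the same values and stays open, as untested.

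Short genes had extreme ratios. Of the 103 features of at most 200 bases counted as 2-fold different, 75.7% had authors' bounds that overlap, which is consistent with few fragments behind each value. The without-fermentation library was thinned to the other's depth. The median centred log2 ratio of the 71 features of at most 150 bases went from -2.31 to -0.41. Of these 71, 33 were listed at 0 with fermentation, and 41 were at 0 without it after thinning (13 before). Some were then at 0 in both libraries, with no fragments behind their ratio. Thinning empties features on so few fragments, so the new median cannot show whether the depth gap gave their downward lean. The draws may also leave the thinned library the shallower one within features, so the size of the change in the median is uncertain. No biological explanation was tested for these features.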
